A study of Homo sapiens with 30 samples.

How the data were processed

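RNA sequencing measured the reads per gene in 30 libraries of 3 established human cancer lines: FaDu, a squamous carcinoma line of the hypopharynx, HCT116, a colon carcinoma line, and SiHa, a squamous carcinoma line of the cervix. Each line was grown in medium at pH 7.4 or at pH 6.5, and cells at pH 6.5 had been kept there for at least 1 month. Each of the 6 groups held 5 libraries. The medium held 10 mM glucose, 2 mM glutamine, 10% serum and, as buffers, 25 mM HEPES and 25 mM PIPES. Cultures were kept at 37 °C and 5% CO2. The labels do not say whether the libraries of a group came from separate cultures, or how many separately adapted populations there were at pH 6.5, so p-values measure the spread between these libraries.

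The submitters' notes name bcl2fastq 2.20, FastQC, Trimmomatic 0.38, STAR 2.6.1d, DESeq2 1.22.2 and the build GRCh37. The program that counted reads, the strand setting and the annotation release are not given in the sources used here. The deposited table held 1 value per library for 38122 Ensembl genes, in the unit signal. These values were normalised counts: every value of a library was a whole multiple of the smallest value above 0, within 0.01 of a step, so whole reads were recovered by dividing by that step. The size factors recovered in this way equalled the median of ratios computed over all 30 libraries. Symbols for 35466 identifiers came from a reference annotation on another build, so genome coordinates were not used, and 2656 identifiers without a match kept only their Ensembl name. Libraries held 21.0 to 55.7 M reads. A count of 0 allows up to 3 reads, or 1.90 to 5.01 normalised counts depending on the library. This limit covers counting error only, since reads without molecular identifiers are not independent molecules.

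Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. The tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. In each line, limma with an intensity trend compared log2 of the normalised count plus 1 between the pH groups. Genes were tested where the mean was at least 10 in the higher group, and changes were called at a Benjamini-Hochberg adjusted p under 0.05 in a 2-sided test. Genes that changed the same way in all 3 lines were counted over the separate fits. The difference of the pH effect between lines was tested with the limma F-test of the interaction in 1 fit over all libraries. Gene lists were tested with limma camera at a preset correlation between genes of 0.01, adjusted over the 29 lists in 3 lines, 87 tests together. Camera with an estimated correlation and limma fry were the alternatives.

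The 29 lists covered secreted factors linked to cachexia or lipolysis, fatty acid uptake, lipid droplets, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, glycolysis, the tricarboxylic acid cycle, the nuclear and the mitochondrially encoded respiratory chain, acid sensing and pH regulation, the lysosome, hypoxia-inducible factor targets, the ATF4 response, endoplasmic reticulum chaperones, NRF2 targets, the cell cycle, p53 targets, epithelial-mesenchymal transition, the TGF-beta response, extracellular matrix, inflammatory cytokines, the interferon response, keratinocyte differentiation, immediate early and heat shock genes, ribosomal proteins, autophagy, Wnt and Notch genes, and sirtuins with histone deacetylases. Marker lists of colon and squamous epithelium, adipocytes, fibroblasts, immune cells and endothelial cells served as checks of identity. List members that were not matched to an identifier, such as LPL, ADIPOQ, ACACA and SOD2, were not analysed here.

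Genes were named by rule. For each line the rule took the 10 genes higher and the 10 lower at pH 6.5 with the largest log2 change among those with adjusted p under 0.05, a mean of at least 100 in the higher group and no overlap between the groups. Up to 4 changed members were taken per list, and every changed secreted factor. The shared and the interaction comparisons contributed 10 genes per direction and 10 genes. Genes named by clone numbers, genes of the Y chromosome and 2 genes of X inactivation were passed over, and 3 genes that the rule names are not reported here.

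The line of each library was checked with genes restricted to 1 line, defined by at least 10 counts per M reads in each reference library of that line (FaDu and SiHa at pH 6.5, HCT116 at pH 7.4) and at most 1% of the lowest of these in each reference library of the other lines. A library was set apart where the genes of another line reached 5% of their own level, or where VIM exceeded 1000. Both limits were chosen after the data were seen, and so were the comparisons that leave these 9 libraries out. Every comparison is given first with the libraries as labelled. The estimate of a line's share was tested on simulated data: 10% of HCT116 reads mixed into FaDu was estimated as 10.8%, and 40% of SiHa reads mixed into HCT116 as 45.6%. These reads came from the reference libraries that defined the restricted genes, so a change of those genes with pH was not tested. The SiHa libraries at pH 7.4 held SiHa genes at 59.6% to 82.8% of their reference level, so a share can be underestimated at the other pH. In simulated data made from the libraries, a 2-fold change was recovered for 73.1% of genes in SiHa, 46.3% in FaDu and 14.9% in HCT116, and a 4-fold change for 100%, 81.8% and 62.1%. With the 9 libraries left out, a 4-fold change was recovered for 100% of genes in SiHa, 92.4% in FaDu and 97.0% in HCT116, and at 2-fold for 70.2%, 23.9% and 71.6%. The interaction test recovered 74.2% of 4-fold differences, or 87.9% without the 9 libraries. At most 11 unchanged genes were called in any of these runs. The simulation drew each gene separately in each library, so it holds no structure that genes of a library share, such as material of another line. Its number of false calls does not carry over to the real libraries, where another split of the FaDu libraries gave 7715 genes.

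Alternatives covered the pseudocount, the filter on low counts, the scaling, robust variance estimates, a replicate block, 1 fit over all libraries, edgeR and DESeq2 on whole reads, and the omission of each library in turn.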

Results

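Reads per gene were measured in 3 human cancer lines, FaDu, HCT116 and SiHa, each kept at pH 7.4 or at pH 6.5, with 5 libraries in each of the 6 groups. The series concerns acidosis in tumours and its link to the loss of fat tissue, so genes for secreted factors and for lipid handling were examined beside the transcriptome as a whole. Values are normalised read counts, given as mean ± SD, and changes are log2 ratios of pH 6.5 over pH 7.4 ± SE. The 5 FaDu libraries at pH 6.5 held 37.4, 50.8, 40.9, 34.0 and 31.6 M reads, and those at pH 7.4 held 34.4, 54.0, 55.7, 48.3 and 36.5 M, in the order of their replicate numbers. HCT116 libraries held 34.2, 30.5, 33.1, 45.1 and 41.8 M reads at pH 6.5 and 36.0, 44.0, 38.4, 31.3 and 33.4 M at pH 7.4. SiHa libraries held 25.4, 25.3, 37.6, 38.9 and 39.7 M reads at pH 6.5 and 34.0, 35.2, 30.1, 28.7 and 21.0 M at pH 7.4. Between 26270 and 31404 genes were detected per library.

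The first comparison asked whether each library carried the genes of the line on its label. SMAD4 (ENSG00000141646), a transducer of TGF-beta signals, was at 0 in FaDu pH 7.4 replicate 1 and at most 3.13 in the FaDu libraries of pH 6.5. In the FaDu pH 7.4 libraries labelled replicates 2 to 5 it stood at 1773, 675, 941 and 1484, and in HCT116 at pH 7.4 at 1800 to 2231. The 31 genes restricted to HCT116 reached a median of 80.5%, 32.7%, 43.6% and 62.0% of their HCT116 level in those 4 libraries, and 0.0397% in FaDu pH 7.4 replicate 1. The 24 genes restricted to FaDu stood at 10.9%, 66.6%, 50.2% and 27.7% of their FaDu level in the same 4 libraries, against 94.2% in replicate 1. The libraries labelled HCT116 pH 6.5 replicates 5, 6 and 7 carried the 27 genes restricted to SiHa at 37.5%, 101% and 104% of their SiHa level. HCT116 genes stood at 59.5%, 1.99% and 0.616% in them, against 98.5% and 97.3% in HCT116 pH 6.5 replicates 1 and 3. In the other 23 libraries the median over the genes of another line was at most 0.0708%.

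**Figure D1:**
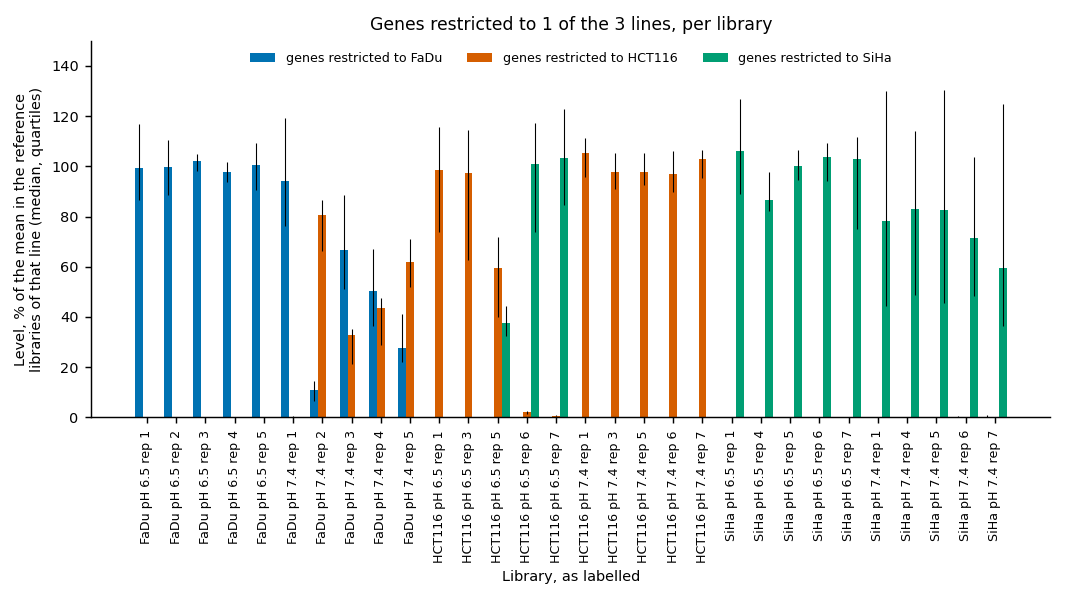
Level of genes restricted to FaDu, HCT116 or SiHa in each of the 30 libraries, as a percent of the mean in reference libraries of that line (bars, median over genes; lines, quartiles). In 4 FaDu pH 7.4 libraries HCT116 genes reach 32.7% to 80.5%, and in 3 HCT116 pH 6.5 libraries SiHa genes reach 37.5% to 104%.

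In SiHa, VIM, an intermediate filament gene of mesenchymal cells, stood at 2817 and 2863 in pH 7.4 replicates 6 and 7, against 2.04, 28.4 and 165 in replicates 1, 4 and 5 and at most 5.60 at pH 6.5. The median over the genes of FaDu or HCT116 was at most 0.0451% in these 2 libraries, with upper quartiles of 0.633% and 1.01% for FaDu genes, of which CDH2 stood at 187 and 279. They are also left out in the second set of comparisons. After this omission 21 libraries remained, with 5 against 3 in SiHa, 5 against 1 in FaDu and 2 against 5 in HCT116. The omission was chosen after the data were seen.

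The SiHa comparison asked how growth at pH 6.5 changed the transcriptome of a cervical squamous carcinoma line. HSD3B1 (ENSG00000203857), which makes steroid hormones from pregnenolone, was at 2015 ± 953 at pH 6.5 and 3.11 ± 2.97 at pH 7.4, a log2 change of 9.29 ± 0.59 (n = 5 per group; limma adjusted p = 1.67e-06). Its pH 6.5 libraries held 3536, 2039, 1966, 1580 and 952 in the order of their replicate numbers, and those of CAPN6 held 1364, 1731, 707, 241 and 103. The mean and SD do not show this order, which AMPH, at 620, 1117, 669, 909 and 1659, did not share. AMPH (ENSG00000078053), which shapes membranes in endocytosis, rose from 2.10 ± 2.07 to 995 ± 421, by 8.51 ± 0.45. FNDC1 (ENSG00000164694), a fibronectin domain protein, rose from 8.46 ± 3.29 to 490 ± 103, by 5.75 ± 0.24. The endocytic receptor LRP2 (ENSG00000081479) stood at 7.33 ± 8.37 against 1443 ± 1602, a change of -7.64 ± 0.84. Its pH 7.4 libraries held 491, 341, 1028, 1107 and 4247, the last in replicate 7, and the change was -6.86 without replicates 6 and 7, with a mean of 620 at pH 7.4. The glycosyltransferase GALNT3 (ENSG00000115339) changed from 459 ± 130 to 14.97 ± 8.12, by -4.97 ± 0.34.

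Other genes of this set that rose in SiHa were the calpain CAPN6 (6.25), the serotonin receptor HTR2C (4.30), the protease inhibitor SERPINA1 (4.15), CBFA2T3 (3.98), SAMD5 (3.70), CCR3 (3.51) and NECTIN3 (3.15). The others that fell were PRRX1 (-5.57), TNFSF15 (-5.36), NRP2 (-5.35), IGHE (-5.01), SOX2 (-4.97), NELL2 (-4.87) and CKMT1B (-4.83). MAGED1 was at 0 in all 5 libraries at pH 6.5 and at 264 ± 368 at pH 7.4. PRRX1, MAGED1, SOX2, TNFSF15, NRP2, NELL2 and CKMT1B, like GALNT3 and LRP2, were highest in pH 7.4 replicates 6 and 7. Without these 2 libraries TNFSF15 stood at -4.48, NRP2 at -4.88, NELL2 at -4.56, CKMT1B at -4.66 and GALNT3 at -4.69, each still called. The means of PRRX1, MAGED1 and SOX2 at pH 7.4 were then 28.1, 12.3 and 20.2 (limma adjusted p = 0.00151, 0.0129 and 0.0197). The 3 libraries left, replicates 1, 4 and 5, held PRRX1 at 9.17, 20.8 and 54.1, MAGED1 at 1.02, 6.63 and 29.3, and SOX2 at 2.04, 12.3 and 46.3. VIM (2.04, 28.4 and 165) and COL1A2 (3.06, 10.4 and 42.9) had the same order, so what raised these genes in replicates 6 and 7 is not shown to be absent from replicates 4 and 5. In this smaller set SOX2 was not called without pH 7.4 replicate 4 (adjusted p = 0.0620), and without pH 7.4 replicate 5 SOX2 and MAGED1 were below the level for testing.

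**Figure D2:**
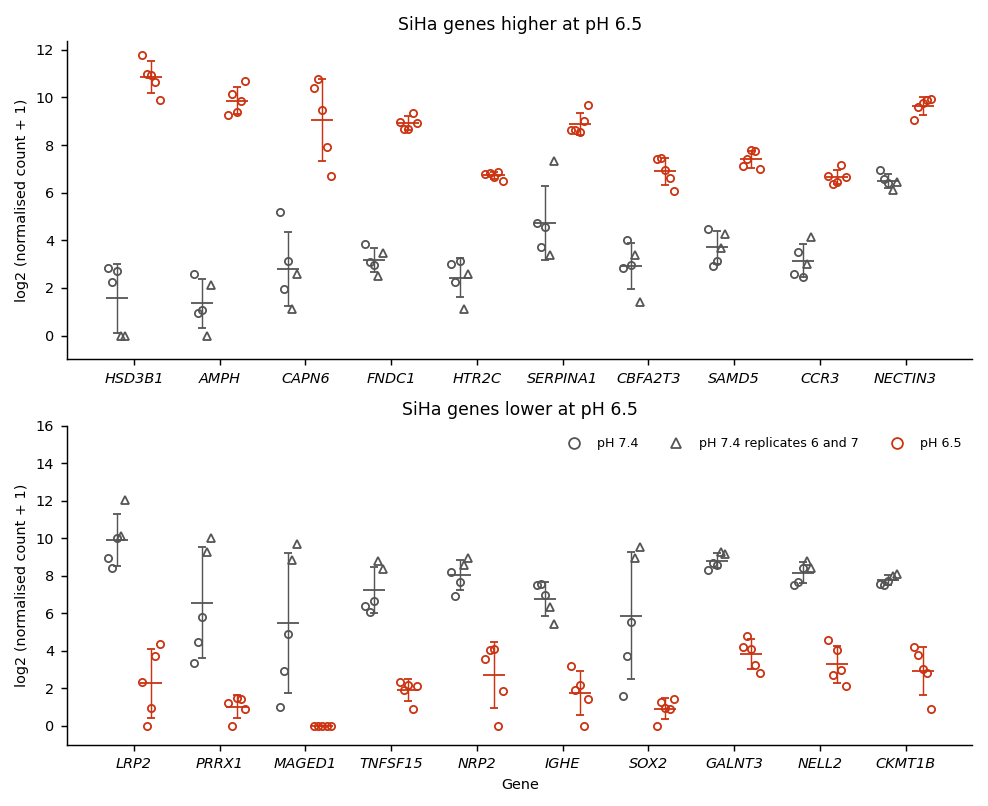
Normalised counts on a log2 scale of the 20 genes with the largest changes in SiHa, 1 point per library, with mean and SD of the 5 libraries of each group. HSD3B1 lies at a mean of 2015 at pH 6.5 and 3.11 at pH 7.4, and triangles mark pH 7.4 replicates 6 and 7, in which 9 of the 10 fallen genes, all but IGHE, are highest.

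Of 64 genes of the cell cycle and DNA replication list, 53 rose and 0 fell in SiHa (57 and 1 adjusted over the list alone; camera adjusted p = 5.8e-14, and adjusted p = 0.919 with an estimated correlation). They included the mitotic phosphatase CDC25C (1.57), the kinase AURKB (1.31), the checkpoint gene BUB1B (1.27) and HMGB2 (1.19). Of 25 cholesterol synthesis genes, 15 rose (18 adjusted over the list alone; adjusted p = 0.000212, or adjusted p = 0.919 with an estimated correlation), among them MVD (0.78), HMGCS1 (0.77) and INSIG1 (0.77). Of 30 p53 targets, 16 fell and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 0.00106, or adjusted p = 0.919 with an estimated correlation), with BTG2 at -1.48, TP53I3 at -1.46, the cyclin kinase inhibitor CDKN1A at -1.41 and FAS at -0.98.

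Of 37 genes of epithelial-mesenchymal transition, 22 fell and 6 rose in SiHa (22 and 7 adjusted over the list alone; camera adjusted p = 0.00513, and adjusted p = 0.919 with an estimated correlation). The polarity gene CRB3 (-4.76) and the cadherin CDH3 (-3.95) fell, as did VIM (-6.15) and the matrix protein SPARC (-4.20), which were highest in pH 7.4 replicates 6 and 7. Without these 2 libraries VIM stood at -3.40 (limma adjusted p = 0.0388), a change that came from pH 7.4 replicates 4 and 5 (28.4 and 165, against 2.04 in replicate 1), and SPARC was below the level for testing. In that smaller set the call of VIM was lost without pH 6.5 replicates 1, 6 or 7 or pH 7.4 replicates 4 or 5, at adjusted p up to 0.187. Of 20 keratinocyte differentiation genes, 12 fell and 2 rose (13 and 3 adjusted over the list alone; adjusted p = 0.00344, or adjusted p = 0.919 with an estimated correlation), including the epithelial transcription factor ELF3 (-4.42), KLK10 (-4.01), SERPINB2 (-3.63) and KRT4 (-2.36). The same 5 lists were called without pH 7.4 replicates 6 and 7, each at adjusted p = 0.953 with an estimated correlation.

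Lipid and pH genes moved in both directions in SiHa. Of 30 secreted factors tested, 7 fell and 0 rose (5 adjusted over the list alone): NPPC (-3.99), WNT5A (-0.90), PDGFA (-0.72), GDF11 (-0.59), VEGFA (-0.41), IL1B (-0.99) and ADM, which stood at 1564 ± 782 against 3720 ± 1507. The call of VEGFA was lost without pH 6.5 replicates 1, 4, 5, 6 or 7 or pH 7.4 replicates 1, 5 or 7 (adjusted p up to 0.107), and that of IL1B without pH 6.5 replicates 6 or 7 or pH 7.4 replicates 1, 6 or 7. That of SPARC, above, was lost without pH 6.5 replicates 6 or 7 or pH 7.4 replicates 6 or 7, over all of these omissions at adjusted p between 0.0510 and 0.107. G0S2, an inhibitor of triglyceride lipolysis, rose by 1.31, and the phosphatidate phosphatase LPIN2 by 1.08, within a list of 29 lipid droplet genes in which 8 rose and 6 fell (9 and 8 adjusted over the list alone). The fatty acid transporter CD36 rose by 1.08 and SLC27A4 fell by 1.04, among 5 genes of fatty acid uptake that rose and 5 that fell out of 20 (5 and 6 adjusted over the list alone). PPARGC1A, a coactivator of mitochondrial genes, fell by 2.58 in a fatty acid oxidation list with 10 higher and 11 lower of 33 (11 and 12 adjusted over the list alone). The carbonic anhydrase CA12 rose by 2.56 and CA2 fell by 3.14, among 4 higher and 5 lower of 27 genes of acid sensing and pH regulation (the same counts adjusted over the list alone).

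The other lists were not called in SiHa, with adjusted p from 0.167 to 0.913 over the 24 lists that missed the threshold, the 5 above included. In fatty acid synthesis 4 genes were higher and 6 lower of 26. In glycolysis the counts were 5 and 10 of 27 with LDHA at -0.94, in the tricarboxylic acid cycle 2 and 13 of 37 with IDH2 at 1.45. In the nuclear respiratory chain they were 13 and 24 of 72, and in its mitochondrially encoded part 2 and 1 of 13. In the lysosome list 21 genes were higher and 14 lower of 58. Hypoxia-inducible factor targets gave 7 and 10 of 40 with DDIT4 at -1.74, and the ATF4 response 13 and 11 of 50 with PHGDH at 1.32. Endoplasmic reticulum chaperones gave 12 and 6 of 39, and NRF2 targets 5 and 11 of 33 with SLC7A11 at 1.25. In the TGF-beta response 6 genes were higher and 8 lower of 38, and in extracellular matrix 8 and 17 of 49 with COL17A1 at -4.16. Inflammatory cytokines gave 4 and 6 of 30 with PTGS2 at 1.85, and the interferon response 12 and 14 of 49 with IFIT2 at -2.56. Immediate early and heat shock genes gave 4 and 4 of 37, and ribosomal proteins 6 and 18 of 76. Autophagy genes gave 6 and 9 of 37 with SQSTM1 at 1.06, Wnt and Notch genes 8 and 11 of 31 with ALDH1A3 at -2.97, and sirtuins with histone deacetylases 8 and 6 of 30. Adjusted over each list alone, the counts in this order were 4 and 6, 5 and 11, 2 and 13, 14 and 25, and 2 and 0. Those from the lysosome on were 22 and 15, 7 and 10, 14 and 11, 13 and 6, 5 and 11, 6 and 8, 9 and 18, 4 and 6, and 12 and 15. Those from immediate early genes on were 3 and 4, 5 and 16, 6 and 9, 8 and 12, and 9 and 6. Median and mean of a list differed in sign for lipid droplets, fatty acid oxidation, the mitochondrially encoded respiratory chain, the lysosome, the interferon response and Wnt and Notch genes, the widest gap being a median of 0.03 and a mean of -0.55 for Wnt and Notch genes.

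In total 3712 genes rose and 3978 fell in SiHa of 18834 tested with limma, and 702 rose and 1496 fell at least 2-fold. In 1 fit over all libraries, 1892 rose and 2290 fell. The values of the 2 groups did not overlap for 5324 genes (28.3%), against 0.794% by chance. Without pH 7.4 replicates 6 and 7, 2775 genes rose and 3012 fell of 18555, and 5497 of the genes called in both comparisons moved the same way while 0 were called in opposite directions. All libraries of the smaller comparison are also in the larger one, so this is no independent test. In that smaller comparison, 1736 genes rose and 1815 fell without pH 7.4 replicate 5, and 1923 fell without pH 7.4 replicate 1.

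The FaDu comparison asked the same of a line of the hypopharynx. With all libraries as labelled, TMEM52B (ENSG00000165685), a membrane protein, was at 782 ± 325 at pH 6.5 and 13.6 ± 24.5 at pH 7.4, a change of 7.08 ± 0.94 (n = 5 per group; limma adjusted p = 0.000472). The imprinted RNA H19 (6.53 ± 1.00), the deiodinase DIO2 (6.19 ± 0.79), which activates thyroid hormone, and the kinase MATK (5.72 ± 0.50) also rose. WNT16 (ENSG00000002745), a Wnt ligand, was at 1.37 ± 0.67 against 2921 ± 2436, a change of -8.61 ± 1.63. In HCT116 at pH 7.4 WNT16 stood at 8009 ± 362, and 4 of the 5 FaDu libraries at pH 7.4 carried HCT116 genes.

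The other top genes that rose with the labels as given were MYL7 (6.62), MIR9-3HG (6.10), CCDC80 (6.05), OLR1 (5.88), CP (5.59) and TMPRSS2 (5.31). Those that fell were HTR7 (-8.09), SLC38A5 (-7.98), NTSR1 (-7.91), MAGEA2B (-7.88), MIR100HG (-7.63), TNFRSF10A (-7.42), BMP4 (-7.15), SDR42E1 (-6.71) and PAX2 (-6.69). NTSR1, MAGEA2B and BMP4 are among the genes restricted to HCT116. With FaDu pH 7.4 replicate 1 alone as the reference, TMEM52B stood at 3.59, DIO2 at 3.57, MYL7 at 4.52, MIR9-3HG at 4.29, OLR1 at 2.31, CP at 2.81 and NTSR1 at -3.19, each still called. Of these NTSR1 and TMEM52B were not called without any of pH 6.5 replicates 2, 3, 4 or 5, nor MIR9-3HG without replicates 3, 4 or 5, OLR1 and CP without replicates 3 or 4, or MYL7 without replicate 4, at adjusted p up to 0.101. H19 stood at 2.69 (limma adjusted p = 0.115), CCDC80 at 3.61 (0.123), TMPRSS2 at 2.41 (0.120) and HTR7 at -5.20 (0.0515), no longer called. Nor were BMP4 at -3.61 (0.0716), MIR100HG at -4.85 (0.133) and SDR42E1 at -4.14 (0.154), while WNT16, SLC38A5, MAGEA2B, TNFRSF10A and PAX2 were below the level for testing. As labelled, 4727 genes rose and 4388 fell of 19690, with 1990 and 2127 at least 2-fold, and 4679 genes did not overlap (23.8%, against 0.794% by chance). Lists called upwards were fatty acid oxidation (17 higher, 5 lower of 36; 18 and 6 adjusted over the list alone), the nuclear respiratory chain (22 and 5 of 72; 20 and 4 adjusted over the list alone) and the interferon response (21 and 1 of 49; the same counts adjusted over the list alone). Lists called downwards were fatty acid uptake (3 and 13 of 24; 3 and 14 adjusted over the list alone), cholesterol synthesis (4 and 15 of 26) and the ATF4 response (3 and 15 of 51), both with the same counts adjusted over the list alone, and endoplasmic reticulum chaperones (2 and 19 of 39; 2 and 20 adjusted over the list alone). Their camera adjusted p ran from 0.000705 to 0.0378, with adjusted p = 0.919 with an estimated correlation for each. With the libraries that carry HCT116 genes left out, the interferon list turned downwards and was not called (0.559), nor were fatty acid oxidation (0.0548), the nuclear respiratory chain (0.246) and fatty acid uptake (0.260). Without pH 6.5 replicate 1 fatty acid oxidation (adjusted p = 0.0534) and the nuclear respiratory chain (0.314) were not called. Without pH 7.4 replicate 4 the nuclear respiratory chain was not (0.0577), and without pH 7.4 replicate 1 cholesterol synthesis (0.0838) and the ATF4 response (0.254) were not. Without pH 6.5 replicate 1 there were 1 list higher and 7 lower, and without pH 7.4 replicate 2 there were 7 lower, against 3 and 4 with all libraries.

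Against FaDu pH 7.4 replicate 1 alone, several genes of the ATF4 and unfolded protein responses were lower at pH 6.5, so each change here rests on that 1 library. INHBE (ENSG00000139269), an activin subunit induced by stress, was at 38.0 ± 10.9 against 900 in that library, a change of -4.59 ± 0.45 (5 libraries against 1; limma adjusted p = 0.00811). NUPR1 (-3.47 ± 0.34), CHAC1 (-3.26 ± 0.37), which degrades glutathione, and the TOR inhibitor DDIT4 (-2.16 ± 0.21) were lower as well. As labelled, with the pH 7.4 libraries that carry HCT116 genes included, INHBE stood at -1.18, NUPR1 at 0.46 and DDIT4 at -0.50, none of them called. CHAC1 then stood at -1.99 and was called. IDH2 (ENSG00000182054), the mitochondrial isocitrate dehydrogenase, was at 8005 ± 1206 against 924, a change of 3.10 ± 0.20. MATK (4.92 ± 0.28), the sulfotransferase CHST6 (4.26 ± 0.44) and RRAD (3.88 ± 0.40) were higher. As labelled, MATK stood at 5.72 and was called, while CHST6 at -0.19 and RRAD at 1.38 were not. This comparison assumes that the lone pH 7.4 library varies as the libraries at pH 6.5 do.

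The list of 51 ATF4 response genes was called downwards in this FaDu comparison, though not with an estimated correlation. FGF21 stood at -4.62, STC2 at -3.43 and SLC7A11 at -1.28, and as labelled at -1.86, -1.94 and -0.37. The list of 39 endoplasmic reticulum chaperones was called downwards too, though not with an estimated correlation. HSPA5 stood at -2.21, HYOU1 at -2.13, CRELD2 at -2.13 and SDF2L1 at -2.02, and as labelled at -0.95, -1.31, 0.0042 and -1.30. Of 34 secreted factors 5 fell and 0 rose (6 and 2 adjusted over the list alone; adjusted p = 0.0144, or adjusted p = 0.953 with an estimated correlation): WNT5A (-5.08), FGF21, VEGFA (-2.16), FGF19 (-1.73) and GDF15 (-1.64). The list test was called downwards for hypoxia-inducible factor targets (7 lower of 41; 11 adjusted over the list alone), NRF2 targets (5 of 34; 8 adjusted over the list alone), autophagy genes (4 of 37; 6 adjusted over the list alone) and cholesterol synthesis (2 of 26; 3 adjusted over the list alone), at adjusted p from 0.0123 to 0.0144, or adjusted p = 0.953 with an estimated correlation. It was called upwards for the mitochondrially encoded respiratory chain (0 of 13 genes; 3 adjusted over the list alone; adjusted p = 0.00345) and the cell cycle (4 of 64; the same count adjusted over the list alone; adjusted p = 0.0429), again at adjusted p = 0.953 with an estimated correlation. The other 20 lists had adjusted p from 0.0548 to 0.867, the interferon response at 0.559. Median, mean and test differed in sign for lipid droplets, the TGF-beta response and sirtuins with histone deacetylases, and for autophagy with all libraries. Cell cycle was not called without pH 6.5 replicates 1 (0.338), 3 (0.0578) or 4 (0.0719), nor NRF2 targets without replicate 1 (0.0633). The number of lists called upwards was 1 without pH 6.5 replicates 1, 3 or 4 and 4 without replicate 2.

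In this comparison of 5 libraries with 1, limma called 812 genes higher and 599 lower of 19170, with 522 and 358 at least 2-fold, and the counts moved with each library left out. FaDu pH 6.5 replicate 1 shared traits with this pH 7.4 library that the other 4 at pH 6.5 lacked, with VIM at 44.8 and 36.3 against 2.08 to 4.42, and SERPINA1 at 1251 and 1418 against 61.8 to 143. Without pH 6.5 replicate 1 there were 3430 higher and 3609 lower, without replicate 2 there were 256 and 128, without replicate 3 there were 45 and 29, without replicate 4 there were 38 and 28, and without replicate 5 there were 220 and 120. Of 68 named genes, 27, 49, 52 and 30 lost their call without replicates 2, 3, 4 and 5, at adjusted p from 0.0501 to 0.121, and 0 without replicate 1. MATK, DIO2, CHST6, RRAD, INHBE, NUPR1, CHAC1, DDIT4, SLC7A11 and IDH2 kept their call under each of these omissions. WNT5A, FGF21, STC2, FGF19, GDF15, VEGFA, HSPA5, HYOU1, CRELD2 and SDF2L1 did not. The lone pH 7.4 library, on which every call rests, could not be left out. A call kept under these omissions therefore says nothing of the spread at pH 7.4. Of 8490 genes called as labelled and tested in both comparisons, 967 (11.4%) had the opposite sign here and 870 were called in the same direction, and log2 changes correlated at r = 0.57 across genes, which are not independent replicates.

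**Figure D3:**
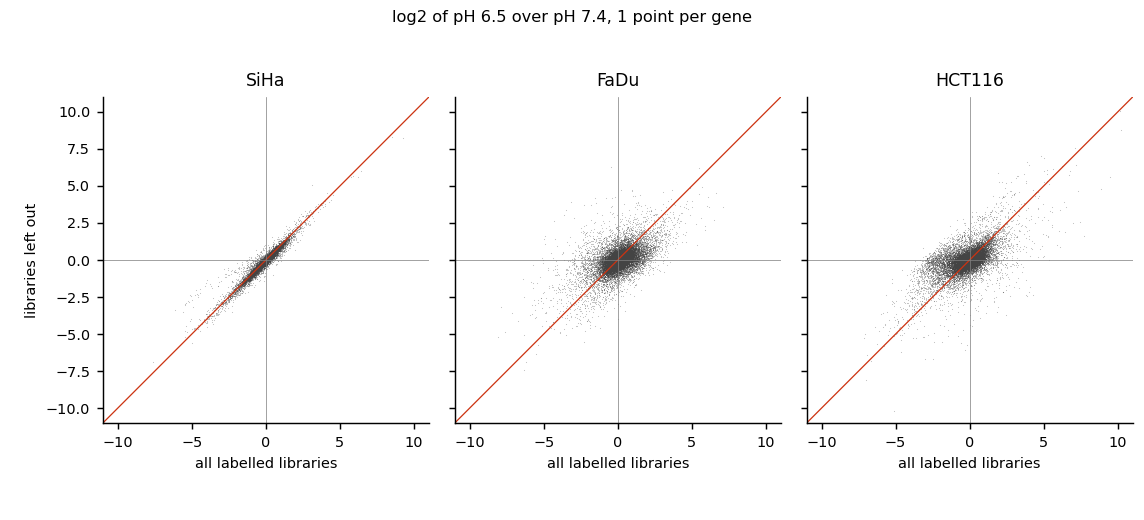
Log2 change of each gene with all labelled libraries (horizontal) against the change with the 9 libraries left out (vertical) in SiHa, FaDu and HCT116, 1 point per gene, with the line of equal change. Changes correlate at r = 0.97 in SiHa, 0.57 in FaDu and 0.63 in HCT116 across genes, which are not independent replicates. Both comparisons of a line share libraries.

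The HCT116 comparison asked the same of a colon carcinoma line. With all libraries as labelled, BST2 (ENSG00000130303), which tethers viruses to the cell surface, was at 11100 ± 631 at pH 6.5 and 9.49 ± 3.97 at pH 7.4, a change of 10.13 ± 0.24 (n = 5 per group; limma adjusted p = 4.9e-09). IFI44L (ENSG00000137959), induced by interferon, was at 1675 ± 1205 against 0 in all 5 libraries at pH 7.4. The membrane dipeptidase DPEP1 (ENSG00000015413) was at 7.16 ± 7.82 against 634 ± 134, a change of -7.15 ± 0.83. HNF4A (ENSG00000101076), a transcription factor of gut epithelium, fell from 621 ± 63.8 to 7.95 ± 4.78, by -6.29 ± 0.36. Of the 5 libraries labelled pH 6.5, replicates 5, 6 and 7 carried SiHa genes.

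The other top genes that rose with the labels as given were RANBP3L (9.51), IFI16 (8.85), EDNRB (8.75), KRT17 (7.45), GBP1 (7.29), APOL1, IFITM1 (7.14) and XAF1 (6.74). Those that fell were ZC4H2 (-7.04), TM4SF18 (-7.03), ZFP42 (-6.93), FLRT3 (-6.67), EPS8L3 (-6.41), DRD1 (-6.10), KLK6 (-5.96) and WNT16 (-5.86). RANBP3L and EDNRB are among the genes restricted to SiHa. Without the labelled replicates 5 to 7, which carried SiHa genes, EDNRB was below the level for testing, and RANBP3L stood at 5.63, IFI16 at 4.83, GBP1 at 4.65 and KRT17 at 2.56. In that smaller set IFI16 (adjusted p = 0.0608) and KRT17 (0.0672) were not called without pH 6.5 replicate 1. As labelled, the calls of EDNRB and KRT17 were lost without single libraries, EDNRB under each omission but those of pH 6.5 replicates 1 and 3, and KRT17 without pH 6.5 replicate 5 or pH 7.4 replicates 3, 5, 6 or 7, at adjusted p from 0.0504 to 0.0891. Limma called 1674 genes higher and 1881 lower of 19557, with 1011 and 1052 at least 2-fold, and 3374 genes did not overlap (17.3%, against 0.794% by chance). In 1 fit over all libraries 4256 genes were higher and 4643 lower. The edgeR test called 4576 genes, 3071 of them higher, and DESeq2 called 6223, 3931 of them higher, so most were higher, unlike in limma. In the separate limma fit the counts were 3365 higher and 3606 lower without pH 6.5 replicate 1, 3099 and 3067 without replicate 3, 943 and 1201 without replicate 5, 867 and 1033 without replicate 6 and 924 and 1110 without replicate 7. Without pH 7.4 replicates 3, 5, 6 and 7 they were 831 and 956, 764 and 879, 730 and 904, and 720 and 861. Scaling to the same total moved the median of all genes by 0.14 on the log2 scale and the share of higher genes among those called from 47.1% to 63.7% (2250 higher and 1281 lower).

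Lists called in HCT116 as labelled were the interferon response (44 higher, 0 lower of 49; 45 adjusted over the list alone; camera adjusted p = 3.1e-34, and adjusted p = 0.192 with an estimated correlation) and inflammatory cytokines (9 and 3 of 33; 15 and 3 adjusted over the list alone; adjusted p = 0.00538, or adjusted p = 0.919 with an estimated correlation), both upwards. The lysosome (13 and 1 of 57; 18 and 2 adjusted over the list alone; adjusted p = 0.00106) and the cell cycle (0 and 1 of 64; 0 adjusted over the list alone; adjusted p = 0.0419) were called upwards too, at adjusted p = 0.919 with an estimated correlation. Fatty acid uptake (0 and 8 of 24; 1 and 8 adjusted over the list alone; adjusted p = 0.0290) and ribosomal proteins (0 and 2 of 76; 0 adjusted over the list alone; adjusted p = 1.5e-06) were called downwards. These 2 lists also had adjusted p = 0.919 with an estimated correlation. The cell cycle list was not called without pH 6.5 replicates 6 (adjusted p = 0.268) or 7 (0.318) or pH 7.4 replicate 1 (0.392). With the labelled replicates 5 to 7 left out, the cell cycle list (0.708) and ribosomal proteins (0.170) were not called and their direction turned. Median, mean and test differed in sign with all libraries for secreted factors, hypoxia-inducible factor targets, the ATF4 response, the TGF-beta response and autophagy.

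With HCT116 pH 6.5 replicates 1 and 3 alone against the 5 libraries at pH 7.4, interferon-induced genes were again among the largest increases. BST2 was at 10470 ± 224 (n = 2) against 9.49 ± 3.97 (n = 5), a change of 10.04 ± 0.34 in limma. IFI27 (ENSG00000165949), a mitochondrial protein induced by interferon, rose from 150 ± 41.2 to 14530 ± 2855, by 6.62 ± 0.24, and IFI6 (ENSG00000126709) from 510 ± 120 to 34970 ± 14870, by 6.06 ± 0.25. HNF4A changed from 621 ± 63.8 to 11.4 ± 4.88, by -5.70 ± 0.23. GDF15 (ENSG00000130513), a stress hormone that lowers appetite, was at 19260 ± 1964 against 6588 ± 1174, a change of 1.56 ± 0.17. As labelled, GDF15 stood at -1.17 and was not called (adjusted p = 0.530).

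**Figure D4:**
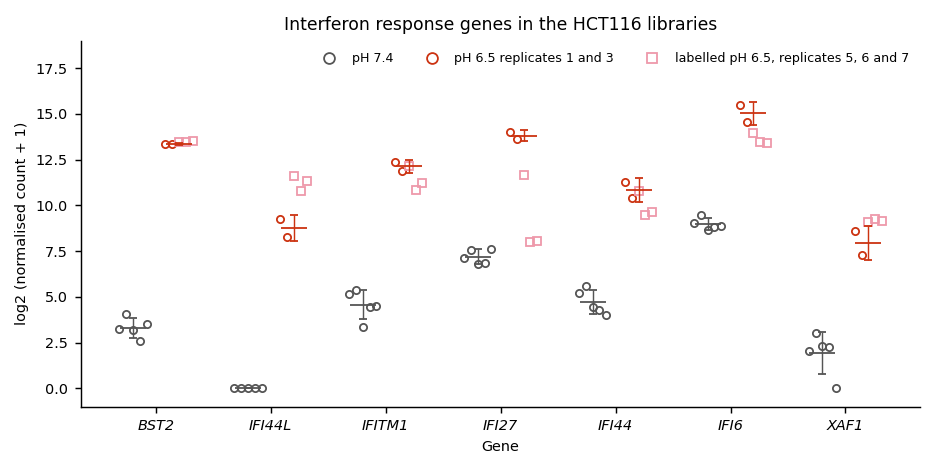
Normalised counts on a log2 scale of 7 interferon response genes in the HCT116 libraries, 1 point per library, with mean and SD of pH 7.4 (n = 5) and of pH 6.5 replicates 1 and 3 (n = 2), and the libraries labelled pH 6.5 replicates 5, 6 and 7 as squares. BST2 lies at a mean of 10470 in replicates 1 and 3 and at 9.49 at pH 7.4.

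Of 49 interferon response genes, 47 rose and 0 fell in this HCT116 comparison (49 adjusted over the list alone; camera adjusted p = 2.9e-49, and adjusted p = 0.953 with an estimated correlation), with IFITM1 at 7.57, IFI44 at 6.14 and XAF1 among the largest. Other top genes that rose were MUSK (6.86), APOL1 (6.41) and KRT4 (5.90), and those that fell were FLRT3 (-6.82), ZFP42 (-6.40), ZNF134 (-5.50), SPATA18 and DPEP1. TM4SF18, ZNF234 and ZNF502 were at 0 in both libraries at pH 6.5 and at 279 ± 49.7, 104 ± 6.90 and 102 ± 20.1 at pH 7.4. Of 26 fatty acid synthesis genes 7 fell and 0 rose (the same counts adjusted over the list alone; adjusted p = 0.0187, or adjusted p = 0.953 with an estimated correlation), including ELOVL6 (-1.51), FASN (-1.10) and SCD (-1.07). Of 26 cholesterol synthesis genes 4 fell and 2 rose (10 and 2 adjusted over the list alone; adjusted p = 0.00345, or adjusted p = 0.953 with an estimated correlation), with LSS at -1.14 and TM7SF2 at 1.29. The list of epithelial-mesenchymal transition was called downwards (11 lower, 4 higher of 31; 13 and 4 adjusted over the list alone; adjusted p = 0.0116, or adjusted p = 0.953 with an estimated correlation), S100A4 at -2.89 and the repressor ZEB1 at 2.22. Since this list pools epithelial with mesenchymal genes, its call gives no direction of the transition itself.

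The list test was called upwards in these HCT116 libraries for the nuclear respiratory chain (11 higher, 1 lower of 72; 9 and 0 adjusted over the list alone; camera adjusted p = 7.3e-05, or adjusted p = 0.953 with an estimated correlation), with ATP5MC1 at 1.36 and NDUFC2 at 1.09. It was called upwards too for the mitochondrially encoded part (1 of 13; the same count adjusted over the list alone; adjusted p = 0.00694) and the lysosome (7 higher, 3 lower of 56; 7 and 2 adjusted over the list alone; adjusted p = 0.0250), and for p53 targets (8 of 30; the same count adjusted over the list alone; adjusted p = 0.0221), with CDKN1A at 1.04 and the cell death gene BBC3 at 0.98. These 8 lists had adjusted p = 0.953 with an estimated correlation, and the other 21 had adjusted p from 0.0577 to 0.838. Median and mean differed in sign for glycolysis, extracellular matrix and sirtuins with histone deacetylases. Of 31 secreted factors, 7 rose and 5 fell (9 and 6 adjusted over the list alone). Beside GDF15, PTHLH (2.63), AZGP1 (2.38), which mobilises lipid, the chemokines CXCL8 and CXCL1 (2.01), PDGFA (1.07) and GDF11 (0.82) rose, while LCN2 (-2.59), TGFB2 (-2.13), CSF2, NPPA (-1.94) and IL1A (-1.58) fell. The acyl-CoA ligase ACSL1 (-2.06) and the lipase LIPG (-1.99) fell, and CA12 rose by 1.03.

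Limma called 1721 genes higher and 2098 lower of 18885 in this HCT116 comparison, with 954 and 1054 at least 2-fold. There were 850 higher and 1348 lower without pH 6.5 replicate 1. Of 3434 genes called as labelled and tested in both, 1979 were called in the same direction and 0 in the opposite one. Both comparisons share the libraries of the smaller set, so this is no independent test. Without pH 6.5 replicate 1, 19 of 91 named genes lost their call (adjusted p from 0.0537 to 0.199), among them CXCL8, CXCL1, PDGFA, GDF11, NPPA, IL1A, CA12, BBC3 and LSS. Without replicate 3, 14 did (0.0501 to 0.365), among them LCN2, CSF2, NPPA, IL1A, BBC3 and LSS. BBC3 and CSF2 were also lost without pH 7.4 replicates 3, 5, 6 or 7, and IL1A without pH 7.4 replicates 3, 5 or 6, at adjusted p up to 0.0851. The lysosome (adjusted p = 0.522), p53 targets (0.305) and the nuclear respiratory chain (0.335) were not called without pH 6.5 replicate 1, fatty acid synthesis (0.197) and epithelial-mesenchymal transition (0.181) without replicate 3, and the lysosome without pH 7.4 replicate 6 (0.0557). Lists higher and lower numbered 5 and 3, but 2 and 5 without pH 6.5 replicate 1, 8 and 1 without replicate 3, and 5 lists were lower without pH 7.4 replicate 1.

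Genes that changed the same way in all 3 lines were counted next, to ask whether acidity had a shared effect. With all libraries as labelled, MYH15 (ENSG00000144821), a myosin heavy chain, fell in each line, by -5.39 ± 0.63 in FaDu, -5.26 ± 0.99 in HCT116 and -2.87 ± 0.39 in SiHa (n = 5 per group in each line; limma). It is one of the genes restricted to HCT116, at 241 in FaDu pH 7.4 replicate 1 and 1108 to 4588 in replicates 2 to 5, so material of another line enters its change in FaDu and HCT116. The growth factor BDNF (ENSG00000176697) stood at -5.60 ± 0.65, -3.55 ± 0.54 and -1.61 ± 0.40 in the same order. HTRA3 (ENSG00000170801), a serine protease, stood at 2.63 ± 0.63, 5.76 ± 1.42 and 1.95 ± 0.27. UBA7 (ENSG00000182179), which activates the ubiquitin-like protein ISG15, stood at 2.68 ± 0.59, 4.92 ± 0.85 and 1.41 ± 0.12. With the libraries that carry another line left out, HTRA3 stood at 0.88 in FaDu (adjusted p = 0.219) and was below the level for testing in HCT116, where replicates 5 to 7 at pH 6.5 held 324, 514 and 568 against 12.6 and 2.28 in replicates 1 and 3. UBA7 then stood at 0.72 in FaDu (adjusted p = 0.341) and 2.67 in HCT116, and BDNF at -3.35 and -2.26. This call of BDNF in FaDu was lost without pH 6.5 replicates 2, 3, 4 or 5, at adjusted p up to 0.103. As labelled, the call of HTRA3 in HCT116 was lost without pH 6.5 replicates 5, 6 or 7 or pH 7.4 replicates 5, 6 or 7. That of ALPG was lost without pH 6.5 replicates 5 or 6 or pH 7.4 replicates 1, 3, 5 or 7, at adjusted p up to 0.0904.

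With all libraries as labelled, 242 genes rose and 236 fell in all 3 lines of 16760, against 76.3 and 67.9 for independent lists. The numbers for independent lists take every gene as equally easy to call. An excess over them, here or with the 9 libraries left out, is therefore not by itself a shared effect. Without a filter 128 rose and 140 fell, and with edgeR and DESeq2 385 and 542 rose. The largest shared increases were in HTRA3, UBA7, CDKN2C, FAT4, ST3GAL3, IFITM1, DMC1, PSMB9, TMEM107 and TMPO-AS1, and the largest shared decreases in MYH15, ALPG, ZNF365, TMEM150C, PAG1, BDNF, CYP4F3, ADGRE2, SERPINB5 and TRIML2. Correlations across genes were 0.43 for FaDu and HCT116, 0.11 for FaDu and SiHa and 0.31 for HCT116 and SiHa, where FaDu libraries at pH 7.4 carried HCT116 genes and HCT116 libraries at pH 6.5 carried SiHa genes. Higher and lower genes numbered 452 and 461 without HCT116 pH 6.5 replicate 1, 446 and 393 without replicate 3, 148 and 141 without replicate 5, 117 and 120 without replicate 6, and 135 and 138 without replicate 7. Without HCT116 pH 7.4 replicates 3, 5, 6 and 7 they numbered 122 and 113, 119 and 111, 109 and 112, and 107 and 110.

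With the 9 libraries left out, MYH15 (ENSG00000144821), a myosin heavy chain, fell in each line, by -2.87 ± 0.33 in FaDu, -2.98 ± 0.12 in HCT116 and -3.07 ± 0.43 in SiHa. The placental alkaline phosphatases ALPP (-3.86, -3.27 and -2.03) and ALPG (-3.04, -4.49 and -2.15), the cholesterol exporter ABCG1 (-2.05, -2.77 and -1.77), S100A14 (-1.33, -2.78 and -1.58) and S100A4 (-1.87, -2.89 and -0.78) fell as well. HES4, a target of Notch (1.55, 1.45 and 0.99), the macrophage growth factor CSF1 (ENSG00000184371; 1.71, 2.41 and 0.98), ARRDC4 (1.39, 2.28 and 0.70) and the lipid transfer protein PLTP (2.74, 1.44 and 0.59) rose in each line. In SiHa pH 7.4 replicates 6 and 7, left out here, ARRDC4 was at 2390 and 2059, against 2014 to 2177 at pH 6.5. Replicates 1, 4 and 5 at pH 7.4 held 1606, 981 and 1343, so with all libraries the groups overlap and the rise is smaller. In pH 7.4 replicate 7, CSF1 (692.5) and PLTP (125) were also within their SiHa pH 6.5 ranges, 372 to 931 and 102 to 177. The calls of CSF1 and PLTP in SiHa and of ALPP, ALPG, ABCG1 and PLTP in HCT116 were lost when any of several single libraries was left out. Those of ALPP, ALPG, ABCG1, S100A14 and ARRDC4 in FaDu were lost in this way too, and every FaDu call rests on the lone pH 7.4 library. In SiHa PLTP was not called without any of pH 6.5 replicates 1, 5, 6 or 7 or pH 7.4 replicates 1, 4 or 5, nor CSF1 without pH 6.5 replicates 4 or 6 or pH 7.4 replicates 4 or 5, at adjusted p up to 0.117. In HCT116 ALPP and PLTP were not called without pH 6.5 replicate 1, nor ALPP, ALPG and ABCG1 without replicate 3, at adjusted p up to 0.198. In FaDu the 5 genes were not called without pH 6.5 replicate 4, all but ARRDC4 also without replicate 3, and ABCG1 also without replicates 2 or 5, at adjusted p up to 0.103.

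With the 9 libraries left out, 24 genes rose and 44 fell in all 3 lines of 15888 tested, against 8.54 and 8.38 for independent lists in limma calls of these sizes. Higher and lower genes numbered 73 and 129 without FaDu pH 6.5 replicate 1, 12 and 16 without replicate 2, 5 and 4 without replicate 3, 3 and 3 without replicate 4, and 12 and 15 without replicate 5. There were 10 higher without HCT116 pH 6.5 replicate 1, 29 lower without HCT116 pH 6.5 replicate 3, and 15 higher without SiHa pH 7.4 replicate 5. Log2 changes of FaDu and HCT116 correlated at r = 0.0073 across genes, those of FaDu and SiHa at 0.083, and those of HCT116 and SiHa at 0.040, and genes are not independent replicates.

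The last comparison asked which genes responded to pH differently between lines. With all libraries as labelled, ZEB1 (ENSG00000148516), a repressor of epithelial genes, stood at -5.20 ± 0.67 in FaDu, 3.84 ± 0.68 in HCT116 and 1.12 ± 0.13 in SiHa (limma F-test adjusted p = 5.6e-08). H19 (ENSG00000130600) stood at 6.53 ± 1.00, -2.07 ± 0.35 and -2.56 ± 0.21 in the same order (adjusted p = 8.9e-08), and SAMD9L (ENSG00000177409), an antiviral gene, at 2.90 ± 0.78, 6.70 ± 0.69 and -1.35 ± 0.36 (adjusted p = 3.4e-06). Once the libraries with HCT116 genes were left out, none of the 3 was called in FaDu, with ZEB1 at -2.76 (adjusted p = 0.101), H19 at 2.69 (0.115) and SAMD9L at 0.21 (0.609). As labelled, the F-test called 9332 genes of 21981, and 1309 were called in opposite directions in 2 lines. Pairwise, 5205 genes differed between HCT116 and FaDu, 6284 between SiHa and FaDu and 4569 between SiHa and HCT116, or 3524, 3302 and 5426 with the 9 libraries left out. The largest gaps as labelled were in BASP1, H19, ZEB1, CBFA2T3, UBQLN2, NEFH, IL7R, TMX3, SAMD9L and SMAD4. SMAD4 stood at -7.05 in FaDu and 0.46 in SiHa, and it was below the level for testing in FaDu once the libraries with HCT116 genes were left out. The calls of BASP1, NEFH and IL7R in HCT116 were lost without single libraries. BASP1 and NEFH lost theirs under each omission but those of HCT116 pH 6.5 replicates 1 and 3, and IL7R without pH 6.5 replicates 5, 6 or 7 or pH 7.4 replicates 3, 5, 6 or 7, at adjusted p from 0.0511 to 0.108.

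With the 9 libraries left out, some interferon-induced genes with large gaps between lines rose in HCT116 and fell in SiHa. The interferon list was not called in SiHa (14 higher, 14 lower of 49; 15 and 14 adjusted over the list alone), where IFITM1 (1.23), PSMB9 (1.16) and UBA7 (1.39) rose. IFIT1 stood at 5.31 ± 0.37 and -1.47 ± 0.32, IFIT3 at 4.59 and -1.52, and IFIT2 at 3.47 and -2.42. SAMD9L stood at 5.77 and -1.19, and the death ligand TNFSF10 (ENSG00000121858) at 5.26 and -2.17. The keratin KRT6A (ENSG00000205420) stood at 5.66 ± 0.60 in HCT116 and -2.95 ± 0.63 in SiHa, a difference of -8.61 for SiHa minus HCT116 (limma F-test adjusted p = 2.4e-06). APOE (ENSG00000130203), a lipoprotein component, rose in FaDu by 2.15 ± 0.25 and fell in SiHa by 3.75 ± 0.31 on the log2 scale (adjusted p = 2.4e-07), as did MYPN and CKMT1B. XAF1 stood at -0.57 in SiHa. Its call and that of SAMD9L there were lost without pH 6.5 replicate 6 or pH 7.4 replicates 1 or 5, that of XAF1 also without pH 6.5 replicates 5 or 7 and that of SAMD9L without pH 7.4 replicate 4 (adjusted p up to 0.148). The call of APOE in FaDu was lost without pH 6.5 replicate 4 (0.0552). In this smaller set the F-test called 7327 genes of 22127, and 527 genes were called in opposite directions in 2 lines.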

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

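Of the tests in this part, only the other splits of the libraries were planned before their results were seen, and the tests of mixed lines, other material, scaling and read number were chosen afterwards. Single libraries lay far from the other 4 of their group, by the gap to the nearest library over the range (above 0.71), in 4 of 78 tests of 13 measures, and chance does so in about 1 in 20 groups. VIM was at 44.8 in FaDu pH 6.5 replicate 1, against 2.08 to 4.42 in the other 4. The mean log2 of adipocyte markers was 3.34 in FaDu pH 7.4 replicate 1, against 4.37 to 4.66 in replicates 2 to 5, which carried HCT116 genes. HCT116 at pH 7.4 stood at 4.57 to 4.96 and FaDu at pH 6.5 at 3.785 to 3.875. The mean log2 of fibroblast markers was 3.08 in HCT116 pH 6.5 replicate 5, against 2.29 to 2.47, and that of squamous markers was 8.05 in SiHa pH 7.4 replicate 7, against 8.82 to 9.08. Among the named genes, 1 library lay apart in 29 of 134 in FaDu pH 7.4 (replicate 1 in 26 of them) and 17 of 134 in FaDu pH 6.5 (replicate 1 in 15). It did so in 12 of 115 in HCT116 pH 7.4, 2 of 115 in HCT116 pH 6.5, and 7 of 132 in SiHa at each pH, where chance gives about 1 in 20.

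The pH effect differed between lines for 9332 genes with all libraries as labelled. The gaps on the log2 scale were 9.56 for BASP1, 8.25 for NEFH, 8.24 for IL7R and 8.05 for SAMD9L between HCT116 and SiHa. They were 9.09 for H19, 8.97 for CBFA2T3, 8.18 for TMX3 and 7.52 for SMAD4 between FaDu and SiHa, and 9.04 for ZEB1 and 8.38 for UBQLN2 between FaDu and HCT116. Of 100 draws of the labels within lines, 1 gave as many genes, the real one, and the highest other gave 2556, so a division of the libraries by chance was excluded. The draws also remove any pH effect that the lines share, so they do not by themselves test a difference between lines. That difference rests on the F-test. Nor do the draws tie the gaps to pH, since the labels also part libraries that carry another line. NEFH is restricted to SiHa, and in FaDu pH 7.4 replicate 1 SMAD4 was at 0 and CBFA2T3 at 7.69, against at least 675 and at least 198 in replicates 2 to 5.

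Other splits of the libraries excluded chance for the genes changed in each line. In FaDu 1 of 100 splits, the real one, gave as many as 9115 genes, and the highest other gave 7715, which puts pH 6.5 replicate 1 with pH 7.4 replicates 2 to 5 and so points to a structure of the samples. In HCT116 1 of 100 gave as many as 3555, and the highest other gave 0. In SiHa 1 of 100 gave as many as 7690, with 0 as the highest other, and without pH 7.4 replicates 6 and 7 it was 1 of 56 for 5787 genes, with 2 as the highest other. For genes changed the same way in all 3 lines 1 of 100 draws gave as many as 478, with 0 as the highest other. Since other splits of HCT116 or SiHa alone gave 0 genes, other draws had almost no way to give shared ones. These draws therefore do not test whether changes are shared beyond the effects within each line. In FaDu, in HCT116 and in all 3 lines together, the labels also part libraries that carry another line, so these counts are not tied to pH alone. For gene lists chance was not excluded. Adjusted within a line, 39 of 100 splits gave as many as the 10 lists of FaDu (highest other 17), 57 of 100 as many as the 8 of HCT116 (15) and 83 of 100 as many as the 5 of SiHa (16).

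In 4 FaDu pH 7.4 libraries and 3 HCT116 pH 6.5 libraries, genes of another line were present, and a response to pH is argued against by the other 3 libraries of these groups, where their median was at most 0.0497%. A mix of 2 lines at 1 share per library gave log2 ratios that correlated with the observed ones at 0.939 or more across genes, which are not independent replicates. A whole library under the wrong label is argued against for FaDu pH 7.4 replicates 2 to 5 and HCT116 pH 6.5 replicate 5, where the genes of the labelled line stood at 10.9% or more. It is argued against for HCT116 pH 6.5 replicates 6 and 7 as a library of SiHa alone, since HCT116 genes had lower quartiles of 1.21% and 0.457% there, above the upper quartile of at most 0.170% in the 10 SiHa libraries, while a SiHa library with a little HCT116 material stays open. On a scale from SiHa at pH 7.4 (0) to SiHa at pH 6.5 (1), 17 genes in the latter 2 had median positions of 1.57 and 1.30, so SiHa material of pH 6.5 is a candidate explanation. Genes with large SiHa changes did not all go this way. HSD3B1 was at 0 in both, and CAPN6 (16.2 and 6.34) and CBFA2T3 (20.8 and 14.3) were below their SiHa pH 6.5 range. AMPH (1670 and 1030), FNDC1, HTR2C, SERPINA1 and CCR3 were within or above theirs. Among genes that fell in SiHa, LRP2 (10.0 and 10.3), GALNT3 (19.3 and 8.71) and NRP2 (3.09 and 4.75) were within their SiHa pH 6.5 range. In SiHa at pH 7.4 they were at least 341, 316 and 119. MAGED1 (49.4 and 16.6), at 0 in SiHa at pH 6.5, was at 2670 to 3359 in HCT116 at pH 7.4. HSD3B1 and CAPN6 were lowest in replicate 7 of SiHa at pH 6.5, at 952 and 103. LRP2, GALNT3 and NRP2 lie with pH 6.5 but HSD3B1, CAPN6 and CBFA2T3 do not, so the pH of that SiHa material is not settled.

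VIM was high in SiHa pH 7.4 replicates 6 and 7, and COL1A2 stood at 938 and 1377 there against 3.06 to 42.9 in the other 3 at pH 7.4. A smaller number of reads is argued against, since VIM was at most 5.60 in the 2 other SiHa libraries with fewer reads than replicate 6. Among 170 raised genes 65.9% were processed pseudogenes, 11.7 times their share of 5.64% among genes at that level, so reads of another organism, aligned to the human genome, may be present. Raised genes were picked as low in the other 3 libraries, a condition that genes at that level did not have to meet. Part of this excess may therefore come from the selection. Human fibroblasts stay open too, since 4 of 10 fibroblast markers lay above the other 3 pH 7.4 libraries in both, and SiHa expressed 8 of the 10 itself, which would hide a small share, though FAP and LUM lay below the other 3, and CDH1 (3405 and 4734 against 1373 to 1772) and EPCAM (1122 and 1063 against 445 to 549), epithelial genes that fibroblasts would not bring, lay above them. No explanation within the SiHa cells themselves was tested for this pattern.

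In HCT116 pH 6.5 replicates 1 and 3, 47 of 49 interferon response genes rose. SiHa material is argued against, since the median member stood 271 times above the level that 1% of SiHa would bring. Scaling is argued against, since the median log2 change was 2.95 with scaling to the same total and 2.90 as deposited. In HCT116 pH 6.5 replicate 5 the members stood at a median of 1.30 times the level of a mix with HCT116 at its pH 6.5 level, against 4.99 times for a mix with HCT116 at pH 7.4. A higher interferon response of HCT116 cells at pH 6.5 may therefore explain the pattern, as a hypothesis found and tested in the same libraries, and the labels do not say how many populations were adapted.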

How the results depend on the processing

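The comparisons that leave out 9 libraries were chosen after seeing the data, and the other alternatives were planned. Over the alternatives, named genes kept direction and side of the threshold in 3308 results, lost the call in 121 and reversed in 1, and gene lists did so in 264, 39 and 3. Counts stayed within 1.5 times in 406 results and moved in 99. With the 9 libraries left out, named genes kept their call in 3114 results and lost it in 306, and lists in 204 and 47. Where no cause is given, the cause was not tested.

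FaDu genes numbered 812 higher and 599 lower with the libraries that carry HCT116 genes left out, which leaves 1 library at pH 7.4. HCT116 genes numbered 593 higher and 814 lower with a replicate block, 4256 and 4643 in 1 fit over all libraries, and 3071 and 3931 higher with edgeR and DESeq2. Leaving out 1 library gave 720 to 3365 higher and 861 to 3606 lower. SiHa genes numbered 1892 higher and 2290 lower in 1 fit over all libraries. Genes shared by all 3 lines numbered 128 higher and 140 lower without a filter, 111 and 116 with the replicate block, 24 and 44 with the 9 libraries left out, and 385 and 542 higher with edgeR and DESeq2. Leaving out 1 library gave 107 to 452 higher and 110 to 461 lower.

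The labels do not say that a replicate number marks a shared culture or day, so the replicate block was an alternative only. Deviations from the group means of same-numbered libraries correlated across genes at 0.0465 to 0.0760 in FaDu, -0.0677 to 0.0911 in HCT116 and -0.0044 to 0.310 in SiHa, where 2 of the 5 pairs passed 0.1 (replicates 1 and 6). Libraries at pH 6.5 correlated best with their own number in 4 of 5 cases in FaDu, 1 of 5 in HCT116 and 3 of 5 in SiHa, and those at pH 7.4 in 4, 3 and 2 of 5. A link by number is at most a hint from the data and was not excluded in any line.

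With an estimated correlation 0 lists were higher and 0 lower in each line, where camera with the preset correlation called 3 and 4 in FaDu, 4 and 2 in HCT116 and 2 and 3 in SiHa. With fry 1 list was higher in each line. In FaDu 7 lists were lower with the 9 libraries left out, and leaving out 1 library gave 1 to 4 lists higher and 3 to 7 lower. With the 9 libraries left out GDF15 in HCT116 stood at 1.56, from -1.17, and 3 lists turned: the interferon response in FaDu (adjusted p = 0.559), and the cell cycle (0.708) and ribosomal proteins (0.170) in HCT116. The number of interaction genes stayed within 1.5 times under each alternative. Depth did not separate the groups: libraries held 21.0 to 55.7 M reads, and a count of 0 allows 1.90 to 5.01 normalised counts.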

Other observations

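The marker lists gave levels per line. The mean log2 of squamous epithelium markers was 12.5 to 12.8 in FaDu at pH 6.5, 13.1 in FaDu pH 7.4 replicate 1, 6.33 to 6.78 in HCT116 at pH 7.4, 7.89 and 7.15 in HCT116 pH 6.5 replicates 1 and 3, 8.05 to 9.08 in SiHa at pH 7.4 and 6.08 to 8.22 in SiHa at pH 6.5. That of colon epithelium markers was 3.93 to 4.86 in HCT116 at pH 7.4, 3.46 and 3.77 in HCT116 pH 6.5 replicates 1 and 3, 1.74 to 2.23 in FaDu at pH 6.5 and 1.46 to 1.86 in SiHa. Fibroblast markers had means of 1.36 to 1.65 in FaDu and 2.10 to 2.54 in HCT116 in the libraries without genes of another line. In those with such genes they reached 1.87 in FaDu and 3.08 in HCT116. Means were 3.001 to 5.29 in SiHa at pH 6.5 and 5.71 to 6.57 in SiHa at pH 7.4. Over all 30 libraries, means were 2.99 to 4.96 for adipocyte markers, 1.76 to 4.28 for endothelial markers and 2.04 to 3.90 for immune cell markers.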
